A study of Arabidopsis thaliana with 119 samples.

How the data were processed

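Whole rosettes of 20 Arabidopsis thaliana accessions were profiled at 3 times of a short-day cycle on Affymetrix ATH1 arrays, whose short probes were designed on the sequence of the accession Col-0. There were 119 arrays in 60 groups of accession and time point, 59 of them with 2 arrays and 1 (Cvi at the end of the night) with 1. The labels call the arrays of a group biological replicates, each a pool of 5 rosettes. The deposited values are log2 expression values for 21329 probe sets, summarised with RMA per the submitters' processing notes, and the version of that tool is not given in the sources used here. RMA corrects background, quantile-normalizes the arrays and fits 1 value per probe set by median polish. The deposited log2 values ran from 2.05 to 13.7, array medians from 5.64 to 5.75, and the largest gap between 2 arrays at the same quantile was 0.403, so the arrays were on a common scale.

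Of the 21329 probe sets 61 were array controls and were left out, and no filter on dim probe sets was used, leaving 21268 tested. Genes were named from the platform's annotation table and the TAIR10.1 gene table. A single gene was listed for 12594 probe sets, several for 439 and none for 8235, and only single-gene probe sets were named (12445 genes). Of the single-gene probe sets 12520 matched a locus of the gene table and 74 did not. Where a gene had several such probe sets, the one with the highest mean stood for it. The further probe sets of AT2G30600, nad5 and AT1G31690 had the same direction, while 4 of those of nad1 had the opposite one in at least 1 comparison.

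The authors' normalization was kept. For the comparisons of time points the 2 arrays of each accession and time point were averaged, so that the accession was the unit of replication (n = 20), and limma 3.58.1 in R 4.3.3 was fitted with accession and time point as terms and 38 residual degrees of freedom. A second limma fit held the 119 arrays in 60 groups (59 residual degrees of freedom). It gave moderated F tests of differences between accessions at each time, F tests of the accession by time point interaction, and changes within each accession. All p-values were adjusted by Benjamini-Hochberg over the 21268 probe sets, passing means an adjusted p under 0.05, and at least 2-fold means passing with an absolute log2 change of at least 1. The p-values of the second fit measure the spread between the replicates of a group, and the labels do not say whether replicates were grown apart.

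The design, the alternatives, 23 gene lists and the rule for named genes were fixed before the data were examined. Of the 383 members of those lists 67 were measured by a named probe set, and 9 lists had the 3 members needed for a test. These held 3 of 16 members for starch synthesis, 4 of 18 for flavonoids, 8 of 24 for amino acid breakdown and 13 of 25 for autophagy. For nuclear photosynthesis they held 8 of 44, for chlorophyll synthesis 5 of 19 and for ribosome assembly 3 of 10. For cytosolic ribosomal proteins they held 4 of 16 and for cell wall growth 5 of 17. Statements on measured members do not cover the rest of a list. Another 21 lists were therefore made from the named genes after the name table was read and before any comparison was computed: the sugar-repressed, cold and dehydration, cell division, glutathione transferase, plastid redox, organelle-encoded, wide ribosomal protein and further groups. The 30 lists were tested in 3 comparisons (90 tests) with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 90 tests. Several lists share members, such as MGL in amino acid breakdown and sugar repression. The planned starvation score could not be run, because 1 of the 25 members of its list was measured. The 9 sugar-repressed transcripts took its place, and 1 of the 6 planned relations was not run (2 measured members). Score differences and correlations across accessions were tested with 100000 permutations, two-sided.

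Genes were named by rule. For each time comparison these were the 8 largest rises and the 8 largest falls that passed and had the same sign in all 20 accessions, with up to 2 rising and 2 falling members of each list. For each F test they were the 10 smallest p values, with passing members of the glucosinolate, flowering, salicylate defence and starvation lists. Of 9 genes to be named in every case GI had a named probe set, and the other 8 are not analysed here. DPE1, PWD, RCA, SBPASE, PYK10 and EXPA7 come from lists with 2 measured members. AT1G73600 and other genes given as examples of the combined classes were chosen after their values were seen. The level of 5 and the 2 transcripts plotted per array (AT3G15310 and AT5G04380) were also chosen after the values were seen.

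Alternatives covered array centring, renewed quantile normalization, a filter on dim probe sets, other limma models, each replicate number, array or accession left out, and other list tests. Both fits were tested on simulated data with the real groups and 21268 probe sets. Of 100 probe sets given a change of 0.5 at EN against ED 98 were recovered, and 100 of 100 at a change of 1, with 8 false calls. For differences between accessions at EN, 84 of 100 were recovered at a size of 1 and 100 of 100 at 2, with 10 false calls. For the interaction from EN to XN, 50 of 100 were recovered at 1 and 98 of 100 at 2. Of 100 simulated lists of 20 probe sets given a shift of 0.3, 100 were called at EN against ED, with 1 false call among unchanged lists. The members of these lists varied independently, so the false-call rate of real lists, whose members may be correlated, was not measured. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.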

Results

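Transcript levels were measured on Affymetrix ATH1 arrays in whole rosettes of 20 natural accessions of Arabidopsis thaliana, inbred lines collected at different sites and named here as in the labels (Ang0, Bla11, Br0, Bsch2, Bu2, C24, Col0, Cvi, Da0, Ei2, Hl3, Kl0, Kn0, Lip0, Mh1, Old1, Petergof, RRS7, Van0 and Wei1). Plants grew for 5 weeks in 8 h of light and 16 h of darkness, at 160 µmol of photons per square metre and second and 20 °C, and each sample pooled 5 rosettes. Harvests were at the end of the day (ED, 8 h after lights on), at the end of the night (EN, 24 h) and 6 h into an extension of the night (XN, 30 h). There were 40 arrays at ED, 39 at EN and 40 at XN, with 2 biological replicates per accession and time point except for Cvi at EN, which had 1. Arrays of the same accession and time point correlated at r = 0.985 to 0.997 (median 0.994, over 59 pairs and all probe sets), and each array had an array of its own accession as its nearest neighbour over the 1000 probe sets that varied most once the time point means were taken out. Over all probe sets, each array followed the mean of its own time point in the other accessions best. Array medians ran from 5.64 to 5.75 on the log2 scale, and the precision is limited by the number of arrays. Changes below are log2 differences averaged over the 20 accessions, and ± is the SD of the change over the 20 accessions.

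The first comparison, EN against ED, asked which transcripts change over a normal night. GI, an evening component of the circadian clock, fell by 4.62 ± 0.20 and was lower in 20 of 20 accessions (limma adjusted p = 3.7e-41). The largest fall with a name was in AT1G56300, a DnaJ-domain protein, at -6.32 ± 0.24, or 79.8-fold lower (adjusted p = 4.6e-44), followed by AT4G16146 (-5.81), AT5G62360, of the invertase and pectin methylesterase inhibitor family (-5.19), AT2G39920 (-5.04), AT4G30650, of a low-temperature and salt responsive family (-4.85), AT1G07050, a CCT-motif protein (-4.75), and AT1G51090 (-4.31). The largest rises with a name were in AT2G41250 at 5.06 ± 0.40, or 33.5-fold (adjusted p = 8.7e-37), in AT1G64500, a glutaredoxin family protein (4.06 ± 0.27), in HYH, a bZIP transcription factor of light signalling (3.89 ± 0.39), in AT1G68440 (3.81), in AT5G15950, an S-adenosylmethionine decarboxylase (3.11), in AT4G15430 (3.09), in AT1G55960 (3.07) and in AT5G48490, a lipid transfer family protein (3.05 ± 0.55). Each of these 16 transcripts moved the same way in all 20 accessions.

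Of 16 starch synthesis genes listed 3 were measured, and all 3 fell (median -1.02, 3 of 3 when adjusted over the list alone). Among them were the ADP-glucose pyrophosphorylase large subunits APL3 (-1.76 ± 0.40) and APL4 (-1.02 ± 0.43). The limma camera test of that list gave an adjusted p of 0.00397, and an adjusted p = 0.230 with an estimated correlation. Of starch breakdown, 2 transcripts were measured, too few for a list test, and both fell: the disproportionating enzyme DPE1 by 2.44 ± 0.22 (limma adjusted p = 5.9e-38) and the phosphoglucan water dikinase PWD by 1.68 ± 0.31 (adjusted p = 3.5e-27). The sugar transporter SWEET2 rose by 2.78 ± 0.36 (adjusted p = 2.0e-29), and TMT2, a vacuolar monosaccharide transporter, fell by 1.36.

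Of 14 cold and dehydration responsive transcripts, 9 fell and 1 rose (median -0.82; camera adjusted p = 0.000892; adjusted p = 0.0930 with an estimated correlation). COR15B and COR15A, cold-regulated chloroplast proteins, changed by -4.3 ± 0.62 and -3.45 ± 0.87. Of 95 cytosolic ribosomal protein transcripts 64 fell and 8 rose, with a median of -0.13 (camera adjusted p = 0.000125; adjusted p = 0.673 with an estimated correlation), and AT4G30800 (-0.82) and AT5G39850 (-0.67) fell most. Probes of near-identical ribosomal protein copies can share signal, so single members of that family are uncertain. Of 20 DNA replication, histone and mitosis transcripts 16 fell and 3 rose (median -0.26; camera adjusted p = 0.00309; adjusted p = 0.401 with an estimated correlation), with 3xHMG-box2, a chromosomal HMG-box protein, at -0.99 ± 0.23 and the replication factor PSF2 at -0.69.

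Transcripts encoded in the plastid genome gave a higher signal at EN. A higher signal, here and at XN, can come from more plastid RNA or from more of it entering the labelled material. These were not told apart. Of 35 photosystem, cytochrome, ATP synthase and Rubisco transcripts encoded there, 31 rose and 0 fell, with a median of 0.42 (camera adjusted p = 2.1e-06; adjusted p = 0.317 with an estimated correlation). The photosystem I assembly factor ycf4 rose by 1.29 ± 0.35 and rbcL, the large subunit of Rubisco, by 1.16 ± 0.38. Of 20 plastid-encoded ribosomal protein and RNA polymerase transcripts 19 rose (median 0.47; camera adjusted p = 5.2e-06; adjusted p = 0.317 with an estimated correlation), including rpl20 (1.19) and rpl14 (1.04), and of 10 plastid NADH dehydrogenase-like complex transcripts 9 rose (median 0.50; camera adjusted p = 0.00381; adjusted p = 0.401 with an estimated correlation), led by ndhH (1.1) and ndhE (0.95). Among nuclear genes of photosynthesis, 8 light-harvesting and photosystem transcripts gave 2 rises and 3 falls (2 and 3 when adjusted over the list alone; camera adjusted p = 0.892). The Calvin cycle transcripts RCA (0.21) and SBPASE (0.32) rose, and PORB, a light-dependent protochlorophyllide reductase, fell by 2.3 ± 0.36.

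Over all transcripts, 12291 of 21268 probe sets (57.8%) passed an adjusted p of 0.05 in limma at EN against ED, 6271 higher and 6020 lower. At least 2-fold changes were found in 483 probe sets upwards and 499 downwards, and 475 and 475 of these had the same sign in all 20 accessions. Among 6 root markers 0 rose and 1 fell (camera adjusted p = 0.957). This was JAL22, a jacalin-related lectin, at -0.26 (limma adjusted p = 0.00070), while PYK10 differed by 0.06 (adjusted p = 0.43) and EXPA7 by 0.07 (adjusted p = 0.19). The 9 measured sugar-repressed transcripts, genes known to be induced when carbon runs short, went both ways, 4 up and 3 down (median 0.05; camera adjusted p = 0.339), with AT4G27450 at 2.14 ± 0.51 and AILP1 at -1.05 ± 0.39. With an estimated correlation 0 of the 90 camera tests of the 3 comparisons passed (15 at an unadjusted p under 0.05), while fry, a limma test of each list on its own, called 75. Of the 21268 probe sets 8235 had no gene listed in the name table used here, so the groups are incomplete.

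The second comparison, XN against EN, asked what 6 h of further darkness changes after the normal end of the night. The 9 sugar-repressed transcripts all rose, with a median of 2.78. They included AKINBETA1, a regulatory subunit of the SnRK1 energy-sensing kinase (2.34 ± 0.27, limma adjusted p = 1.2e-31), AT4G27450 (2.90 ± 0.52), MGL, a methionine gamma-lyase (2.88 ± 0.53), and AT3G15630 (4.14 ± 0.42, or 17.7-fold). The camera adjusted p of that list was 1.6e-06, and the adjusted p = 0.0930 with an estimated correlation. Of 8 enzymes of amino acid breakdown 6 rose and 1 fell (the same counts when adjusted over the list alone; median 1.98; camera adjusted p = 0.000892; adjusted p = 0.214 with an estimated correlation). MCCA, the methylcrotonoyl-CoA carboxylase subunit of leucine breakdown, rose by 4.03 ± 0.41, or 16.3-fold (limma adjusted p = 7.0e-38), and AT5G09300, a subunit of the branched-chain keto acid dehydrogenase, fell by 0.54. Of 13 autophagy transcripts 11 rose and 1 fell (the same counts adjusted over the list alone; median 0.71; camera adjusted p = 0.000102; adjusted p = 0.242 with an estimated correlation), with the ATG8 family members ATG8E at 1.65 ± 0.31 and APG8A at 1.12 ± 0.24.

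Of the 499 probe sets at least 2-fold lower at EN, 157 then rose at least 2-fold at XN. AT1G56300 rose by 4.62 ± 0.44 (24.7-fold), GI by 3.31 ± 0.35 (limma adjusted p = 2.5e-35), Fes1B, an Hsp70 co-chaperone, by 2.39, and PORB by 1.73. Of the 14 cold and dehydration responsive transcripts 10 rose and 0 fell (median 0.31, mean 1.03). The camera adjusted p was 0.00309, and the adjusted p = 0.137 with an estimated correlation. Set against ED, the same list at XN had 5 rises and 5 falls (median 0.02, camera adjusted p = 0.993). There 2 members were at least 2-fold higher and 4 at least 2-fold lower. The rises from EN to XN were led by the dehydrin LTI30 (4.09 ± 0.80) and COR15B (2.79 ± 0.62). The other largest rises with a name were AT3G62550, a universal stress protein family member (4.34 ± 0.69), AT2G30600, a BTB/POZ-domain protein (4.3 ± 1.06), CCL (3.92 ± 0.63) and AT4G23870 (3.58). The auxin-related IAA29 and WES1, an auxin-conjugating enzyme, rose by 2.56 ± 0.49 and 2.53 ± 0.43. In the plastid NADH dehydrogenase-like complex 7 of 10 transcripts rose (median 0.30; camera adjusted p = 0.0362; adjusted p = 0.555 with an estimated correlation), led by ndhJ (1.66) and ndhK (1.45). Without the dimmest probe sets (the lowest 1 in 3 by mean) that list's camera adjusted p was 0.0969, and the call was also lost without replicate 2.

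HYH fell by 4.05 ± 0.29, or 16.5-fold (limma adjusted p = 7.0e-38), the phosphoethanolamine methyltransferase AT1G73600 by 3.44, AT2G15020 by 3.42, the S-adenosylmethionine decarboxylase AT5G15950 by 3.22, AT2G41250 by 3.12, the sucrose-phosphate synthase ATSPS4F by 3.11 ± 0.59, the lectin AT5G03350 by 2.95 ± 0.86 and the strictosidine synthase-like AT3G57020 by 2.94. Of 18 flavonoid pathway transcripts listed 4 were measured, and all 4 fell (4 of 4 adjusted over the list alone, median -1.42). The camera adjusted p was 0.0385, and the adjusted p = 0.416 with an estimated correlation. These falls included the flavonol glycosyltransferases UGT78D1 (-1.79 ± 0.67) and UGT78D2 (-1.43 ± 0.26). The flavonoid call was lost without the dimmest probe sets (camera adjusted p = 0.104). Of 12 glutathione transferases 6 fell and 0 rose (median -0.15; camera adjusted p = 0.0243; adjusted p = 0.203 with an estimated correlation), with GSTU20 at -1.90 and GSTU27 at -1.86. Of 9 plastid thioredoxin and peroxide-detoxifying transcripts 7 fell and 1 rose (median -0.39; camera adjusted p = 0.00398; adjusted p = 0.203 with an estimated correlation), among them NTRC, a plastid NADPH-thioredoxin reductase (-1.25 ± 0.24), and SAPX, an ascorbate peroxidase (-1.18 ± 0.22). The sugar exporter SWEET11 fell by 1.99 and SWEET2 by 1.54. LHCB4.3 (-1.68), SBPASE (-0.95) and the ribosome assembly factor AT3G15460 (-1.89 ± 0.20) fell as well, although the 8 nuclear light-harvesting and photosystem transcripts (3 rose and 4 fell, also when adjusted over the list alone) and the 3 ribosome assembly transcripts (0 and 3) gave camera adjusted p values of 0.428 and 0.0969.

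In total 14033 probe sets (66.0%) passed in limma at XN against EN, 6661 higher and 7372 lower. Which direction held more probe sets depended on the normalization in all 3 time comparisons. Of these, 716 were at least 2-fold higher and 718 at least 2-fold lower, 700 and 696 of them with the same sign in all 20 accessions. Among 6 root markers 3 fell and 0 rose (camera adjusted p = 0.428). JAL23, another jacalin-related lectin, fell by 2.03 ± 0.97 (limma adjusted p = 5.6e-13) in 20 of 20 accessions, JAL22 by 0.28 (adjusted p = 0.00021) and EXPA7 by 0.11 (adjusted p = 0.036), while PYK10 was at -0.11 (adjusted p = 0.12). The harvests were 6 h apart, so extended darkness and time of day changed together.

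The third comparison, XN against ED, set plants 6 h into an extended night beside plants at the end of the light period. The harvest at 30 h falls at a clock time 2 h earlier in the cycle than the harvest at 8 h. AT4G27450 rose by 5.04 ± 0.33, or 33.0-fold (limma adjusted p = 1.1e-37), AT2G20670 by 4.96 ± 0.55, MCCA by 4.86 ± 0.30 (adjusted p = 5.7e-41), AT1G22890 by 4.52, AT1G54740 by 4.51, SIS, named for salt induction, by 4.18, IAA29 by 4.13 ± 0.44 and AT4G23870 by 4.13. AT1G73600 fell by 4.83 ± 0.41, or 28.5-fold (adjusted p = 1.7e-38). Further falls were seen in the copper amine oxidase AT1G31690 (-4.83), AT1G07050 (-4.72), the GDSL-type lipase AT1G28610 (-3.65), AT1G13470 (-3.61 ± 1.25), AT1G68600, of the aluminium-activated malate transporter family (-3.60), AT5G03350 (-3.59 ± 1.55) and AT5G35735 (-3.57). GI was -1.31 ± 0.42 (adjusted p = 6.9e-21), a smaller difference than in either single step.

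Of the sugar-repressed transcripts 8 rose and 1 fell between ED and XN (median 3.65; camera adjusted p = 6.4e-05; adjusted p = 0.203 with an estimated correlation), with AKINBETA1 at 4.08 ± 0.27 and MGL at 3.85. Amino acid breakdown had 6 rises and 1 fall (also when adjusted over the list alone; median 2.24; camera adjusted p = 0.00381; adjusted p = 0.242 with an estimated correlation). Autophagy had 10 rises and 2 falls (11 and 2 when adjusted over the list alone; median 0.99; camera adjusted p = 0.000148; adjusted p = 0.242 with an estimated correlation), with ATG8E at 3.22 ± 0.33. Starch synthesis had 3 falls of 3 (also when adjusted over the list alone; median -1.13; camera adjusted p = 0.0241; adjusted p = 0.30 with an estimated correlation), with APL3 at -2.01. Of the plastid-encoded transcripts, 30 of 35 for photosynthesis rose and 1 fell (median 0.38; camera adjusted p = 0.000125; adjusted p = 0.456 with an estimated correlation). For plastid gene expression 19 of 20 rose and 1 fell (median 0.48; camera adjusted p = 0.000306; adjusted p = 0.460 with an estimated correlation), with rpl14 at 2.12 ± 0.58. In the plastid NADH dehydrogenase-like complex 9 of 10 rose (median 0.88; camera adjusted p = 0.000434; adjusted p = 0.259 with an estimated correlation), with ndhJ at 1.98 ± 0.61. Of 15 mitochondrially encoded transcripts 11 rose and 1 fell (median 0.22; camera adjusted p = 0.0217; adjusted p = 0.242 with an estimated correlation). Ribosomal protein transcripts had 70 falls and 12 rises of 95 (median -0.20; camera adjusted p = 0.000125; adjusted p = 0.673 with an estimated correlation), and the cell division transcripts 16 falls and 3 rises of 20 (median -0.40; camera adjusted p = 0.00397; adjusted p = 0.416 with an estimated correlation). Plastid redox transcripts had 7 falls and 2 rises (median -0.55; camera adjusted p = 0.0256; adjusted p = 0.259 with an estimated correlation). GSTU20 (-2.52), the cell wall enzymes XTH32 (-2.46) and EXPB3 (-2.32), AT3G15460 (-2.45) and UGT78D1 (-2.14) were among the falls, but their lists did not pass. Of 24 expansins and xyloglucan endotransglucosylases 8 rose and 7 fell (camera adjusted p = 0.883). Of 3 ribosome assembly transcripts 1 rose and 2 fell (camera adjusted p = 0.431). Glutathione transferases had 1 rise and 9 falls of 12, and flavonoid transcripts 0 rises and 4 falls of 4 (camera adjusted p = 0.0590 for each). Of the 6 root markers 2 fell and 0 rose (camera adjusted p = 0.465), JAL23 by 1.82 ± 0.92 and JAL22 by 0.54 ± 0.33.

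At XN against ED, 14863 probe sets (69.9%) passed in limma, 7078 higher and 7785 lower, with 1169 at least 2-fold higher and 1136 at least 2-fold lower. The same sign in all 20 accessions was found for 1145 and 1093 of these. The mitochondrial and plastid redox calls were lost without the dimmest probe sets (camera adjusted p = 0.182 and 0.0768).

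Setting the first step of the dark period (ED to EN) beside the second (EN to XN), 75 probe sets rose at least 2-fold in both, among them AKINBETA1 (1.75 and 2.34) and AT4G27450 (2.14 and 2.90). In both steps 37 fell at least 2-fold, among them AT1G73600 (-1.39 and -3.44). A rise and then a fall was found in 127, such as HYH (3.89 and -4.05) and AT5G15950 (3.11 and -3.22), and a fall and then a rise in 157, such as AT1G56300 (-6.32 and 4.62) and GI (-4.62 and 3.31). Independent lists of these sizes would share 16.3, 16.8, 16.3 and 16.8 probe sets. These values treat each of the 21268 probe sets as equally able to change, dim ones included. All 4 classes, opposite directions included, lay above them, so the excess does not by itself show a link between the steps. In 20 simulations with no change no probe set was called at 2-fold in either step, so they give no chance value for these classes. Both steps use the EN arrays. With replicate 1 at EN used for the first step and replicate 2 for the second, without Cvi, the 4 classes held 80, 32, 128 and 158 probe sets. Across probe sets, which are not independent replicates, the changes of the 2 steps correlated at r = -0.15, against r = -0.50 in the simulations with no change, where the shared EN arrays alone set it. The covariance was -0.0407, against a simulated covariance of -0.00121 and -0.0411 with the EN arrays split.

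The 20 accessions were then compared with each other at each time point, which asks which transcripts differ in level between natural lines. Among transcripts with a name, the one with the smallest p at ED was AT2G25450, a dioxygenase of glucosinolate side-chain hydroxylation, whose accession means spanned 7.64 log2 units, highest in Ang0 and lowest in Mh1 (limma F test, adjusted p = 2.5e-44). AOP3, another glucosinolate side-chain enzyme, spanned 7.22 at ED (adjusted p = 3.0e-38), 6.24 at EN and 3.3 at XN, and BCAT4, of methionine chain elongation in the same pathway, spanned 2.18, 1.90 and 3.13. The serine carboxypeptidase-like scpl42 spanned 4.72 at ED, AT5G38980 spanned 7.15, AT2G01090 4.53, AT5G04380, a methyltransferase of the SABATH family, 4.86, AT2G15130 8.05, the leucine-rich repeat kinase AT3G46370 3.37, AT4G20480 3.19 and AT1G76960 4.33. At EN the smallest p values added AT3G15310 (6.61, highest in Lip0), the thionin THI2.2 (6.12, highest in RRS7), AT5G34920 (4.26) and the resistance gene homologue CSA1 (4.08, highest in Br0). At XN they added AT5G05750 (3.05), AT4G37220 (4.32, highest in Bsch2 and lowest in Ang0), AT2G06490 (2.56), AT5G24480 (4.59), AT5G28430 (2.52) and AT4G03530 (3.98). The sugar-repressed AKINBETA1 differed between accessions at ED (range 0.97, adjusted p = 1.6e-05) and EN (range 0.99, adjusted p = 3.9e-05), and the defensin PDF1.2 at EN (range 3.02, adjusted p = 0.013).

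In the F test 10381 probe sets (48.8%) differed between accessions at ED, 8295 (39%) at EN and 9853 (46.3%) at XN. A range of at least 1 log2 unit was seen in 3218, 3076 and 3527 of these, and of at least 2 in 582, 542 and 580. The counts use 39 arrays at EN and 40 at the other times. Probes were designed on the sequence of Col-0, so a low value can reflect a sequence variant under a probe as well as a low level.

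**Figure D1:**
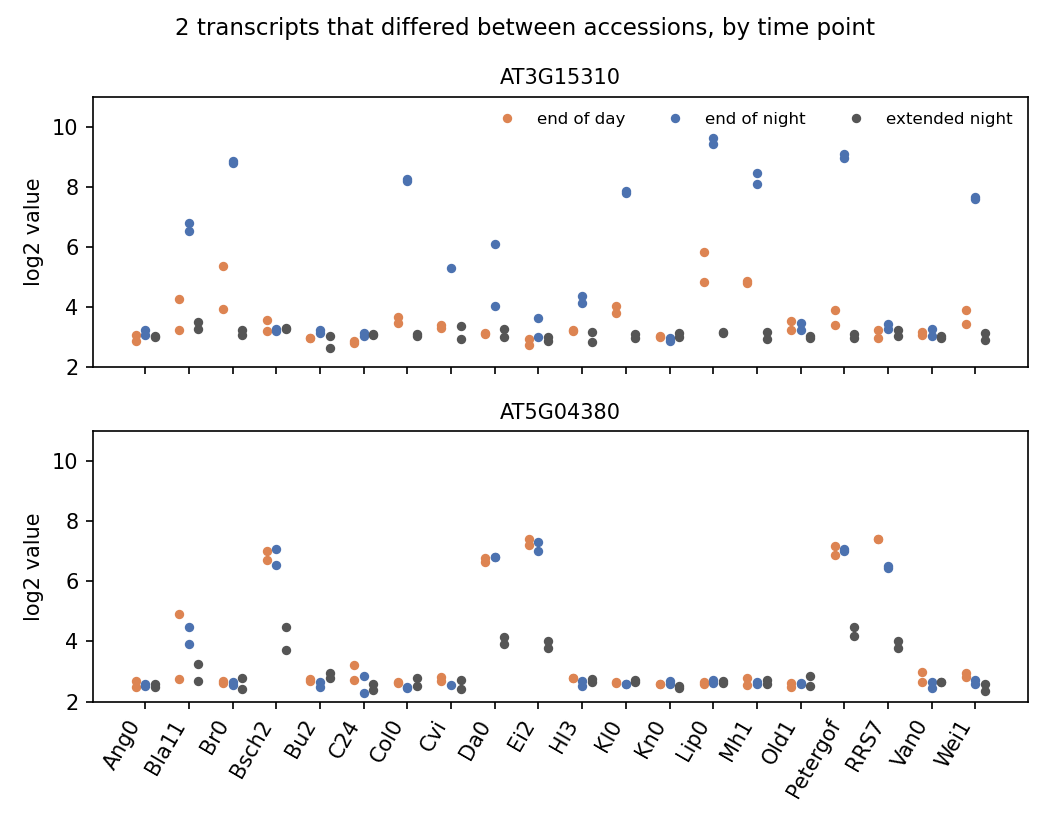
Level (log2) of 2 transcripts in each of the 20 accessions at ED, EN and XN, each point being 1 array. AT3G15310 was above 5 in 1 accession at ED, in 10 at EN and in 0 at XN (means of the accession's arrays), and AT5G04380 was above 5 in 5, 5 and 0 accessions.

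The size of the night response was next compared between accessions with the interaction F test. AT3G15310 had the smallest p among transcripts with a name in both steps (limma adjusted p = 3.4e-26 for ED to EN and 1.7e-32 for EN to XN). Its level at ED, EN and XN was 5.32, 9.52 and 3.15 in Lip0, but 3.02, 2.92 and 3.07 in Kn0. AT5G24210, of the class 3 lipase family, changed by -4.83 in RRS7 and by 0.76 in Lip0 from ED to EN. AT2G29170 went from 8.37 at ED to 3.84 at EN in Br0, but was at 3.64 and 3.75 in Hl3. AOP3 was at 9.21, 5.89 and 5.20 in Bla11 and at 10.9, 10.1 and 6.50 in Wei1, but at 3.83, 4.25 and 4.5 in Ei2. AT4G37220 was at 5.73 at EN and 9.27 at XN in Kl0 and at 5.30 and 5.28 in Ang0, AT3G28310 at 3.67 and 7.35 in Kl0 and at 3.42 and 2.97 in Kn0, and its homologue AT3G28320 showed a range of 3.59. Signal over background was not used here, so the low levels of these transcripts may be background. Where a transcript is low at each time its response cannot be measured, and a change to or from a low level is at least of the size given. AT1G76960, AT3G46370, AT4G03530, AT5G43440, AT5G16380, AT5G42250 and AT3G59480 completed the 10 smallest p values of the first step among named transcripts, with ranges from 1.89 for AT5G16380 to 3.66 for AT3G59480. AT5G04380, AT5G28430, AT4G03530, AT5G43440, AT3G11690 and AT4G18650 completed those of the second, with ranges from 2.50 for AT5G28430 to 3.59 for AT5G04380. AKINBETA1 differed in its rise from ED to EN (range 1.32, highest in Mh1 and lowest in Hl3, adjusted p = 0.0035), and BCAT4 in its fall from EN to XN (range 2.13, adjusted p = 0.0013).

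The interaction passed for 2178 probe sets (10.2%) from ED to EN and for 2087 (9.81%) from EN to XN. Within single accessions, a median of 1127 probe sets changed at least 2-fold from ED to EN, from 967 in Van0 to 1317 in C24, and a median of 1606.5 from EN to XN, from 1163 in RRS7 to 1993 in Ei2. C24 had the most rises from ED to EN (769) and Hl3 the fewest (422), and Br0 had the most falls (698) and Bu2 the fewest (476). From EN to XN, Ei2 had the most rises (1099) and RRS7 the fewest (561), and Hl3 had the most falls (953) and Mh1 the fewest (512). These counts carry no test between accessions, and those of Cvi rest on 1 array at EN.

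**Figure D2:**
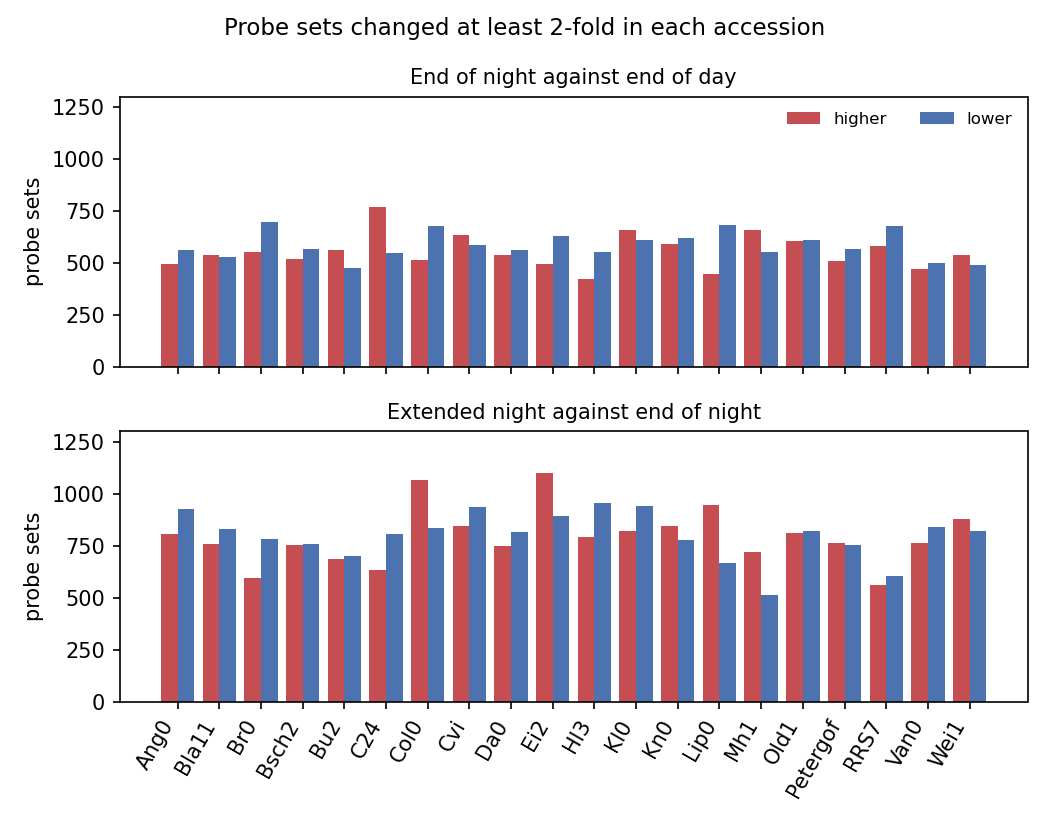
Number of probe sets at least 2-fold higher or lower with a limma adjusted p under 0.05 in each of the 20 accessions, for ED to EN and EN to XN. Totals ran from 967 in Van0 to 1317 in C24 for the first step and from 1163 in RRS7 to 1993 in Ei2 for the second.

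A score was formed as the mean of the 9 sugar-repressed transcripts, each relative to its mean over all arrays, to ask whether accessions differ at dawn and whether other groups follow. Over the 20 accessions the score was -1.14 ± 0.17 (SD) at ED, -0.65 ± 0.24 at EN and 1.77 ± 0.16 at XN. Its rise from ED to EN came from some members, as others fell. At EN it ran from -1.11 in Lip0 to -0.14 in RRS7 (its 2 arrays were at 0.08 and -0.37, so its rank rests on 1 of them), and accessions differed (F = 6.96, permutation p = 3e-05, adjusted p = 4.5e-05, two-sided). At XN it ran from 1.47 in RRS7 to 2.05 in Kl0 (F = 6.97, permutation p = 2e-05, adjusted p = 4.5e-05). At ED the permutation p was 0.0253, also after adjustment over the 3 times. Across accessions, the change of this score from ED to EN went with that of the 7 other amino acid breakdown transcripts (Pearson r = 0.61, permutation p = 0.00392, adjusted p = 0.0196; Spearman rho = 0.68, permutation p = 0.0013, adjusted p = 0.0065; n = 20). MGL, in both lists, was counted only in the sugar-repressed score. Without the 2 accessions farthest from the median of the score's change r was 0.67, and with medians over members in place of means it was 0.44. When the scores came from different arrays of 19 accessions, r was 0.18 with replicate 1 for the sugar-repressed score and 0.74 with replicate 2.

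The remaining 4 relations, of 5 computed, did not pass. The autophagy transcripts gave r = 0.47 (permutation p = 0.0359, adjusted p = 0.0897; rho = 0.44, permutation p = 0.0526, adjusted p = 0.131; without the 2 farthest accessions 0.47). Ribosome assembly gave r = -0.28 (adjusted p = 0.301) and rho = -0.30 (adjusted p = 0.325), the nuclear light-harvesting and photosystem transcripts r = -0.06 (adjusted p = 0.799) and rho = -0.10 (adjusted p = 0.679), and the cell wall growth transcripts r = 0.28 (adjusted p = 0.301) and rho = 0.21 (adjusted p = 0.456), all by permutation over n = 20. Without the 2 farthest accessions these r were -0.40, 0.03 and 0.15, and their unadjusted permutation p values were 0.235, 0.799 and 0.241 for r and 0.195, 0.679 and 0.365 for rho.

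**Figure D3:**
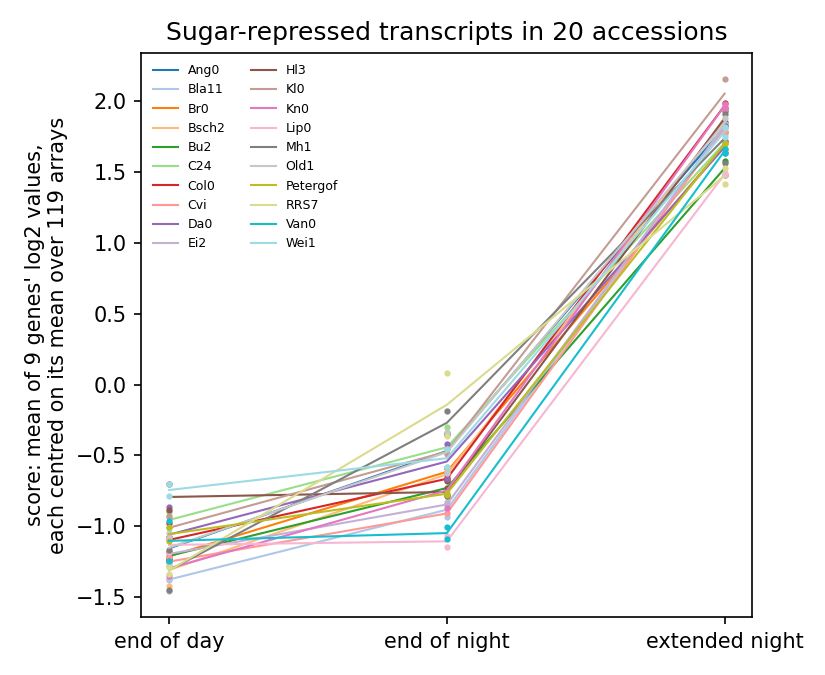
Score of the 9 sugar-repressed transcripts (mean log2 value relative to each transcript's mean over all arrays) in the 20 accessions at ED, EN and XN, with a line through the means of each accession. The means over accessions were -1.14, -0.65 and 1.77, and accessions spanned 0.96 log2 units at EN and 0.58 at XN.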

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

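The test against mitochondrial transcripts was chosen only after the plastid result was seen, as were the comparison sets beside the neighbour test, and the sugar-repressed list was an addition to the planned lists. The other tests in this part were planned. What set these results apart was a response to the night that differed between accessions in the interaction F test of limma, adjusted over all probe sets. This was so for 2178 probe sets from ED to EN and for 2087 from EN to XN. The values below are ranges of the log2 change over the 20 accessions, from the lowest to the highest. They are given for single named transcripts that passed this test, and whether any group of genes passed more often than others was not tested. The ranges of AT3G15310, AT2G29170 and AOP3 include accessions in which the transcript was low at each time, where no response can be measured. The same holds for AT5G04380, AT4G03530, AT5G28430, AT1G76960, AT3G46370, AT3G28310 and AT3G28320. These transcripts are examples and not a complete list.

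From ED to EN, the ranges were 1.32 for AKINBETA1, 1.33 for SWEET2, 1.58 for APL3, 1.65 for APL4, 1.33 for PWD, 3.2 for COR15A, 2.29 for COR15B, 1.87 for AT4G27450, 1.32 for AILP1, 1.13 for MCCA, 1.08 for ATG8D and 1.31 for PORB. Among the largest rises over the night the ranges were 1.36 for AT2G41250, 1.72 for HYH, 1.15 for AT5G15950, 1.06 for AT4G15430, 1.76 for AT1G55960 and 2.45 for AT5G48490. Among the falls they were 1.44 for AT5G62360, 1.41 for AT4G30650, 1.76 for AT1G07050, 2.3 for AT1G51090 and 1.56 for AT1G73600. The glucosinolate transcript AOP3 had a range of 3.74. Transcripts named for their small p in this test had ranges of 3.36 (AT3G46370), 3.51 (AT1G76960), 5.53 (AT3G15310), 2.94 (AT4G03530), 5.58 (AT5G24210), 4.64 (AT2G29170), 3.51 (AT5G43440), 1.89 (AT5G16380), 2.52 (AT5G42250) and 3.66 (AT3G59480).

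From EN to XN, the ranges were 1.94 for MGL, 1.37 for MCCA, 1.69 for AT4G27450, 1.5 for SWEET11, 1.48 for SWEET2, 2.57 for ATSPS4F, 1.69 for IAA29, 1.75 for WES1, 3.18 for LTI30, 2.12 for COR15B, 2.13 for BCAT4, 3.85 for AOP3, 2.56 for UGT78D1, 1.55 for GSTU20, 1.43 for GSTU27, 1.09 for LHCB4.3, 1.53 for PORB and 1.33 for XTH16. Among the largest changes they were 1.38 for AT1G56300, 2.44 for AT3G62550, 3.65 for AT2G30600, 2.56 for CCL, 3.05 for AT4G23870, 2.08 for AT2G41250, 2.92 for AT5G03350 and 1.57 for AT3G57020. Those named for their small p had ranges of 3.59 (AT5G04380), 6.53 (AT3G15310), 3.56 (AT4G37220), 2.50 (AT5G28430), 2.97 (AT4G03530), 3.58 (AT5G43440), 4.13 (AT3G28310), 3.04 (AT3G11690), 3.59 (AT3G28320) and 2.87 (AT4G18650).

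The dependence of the EN to XN change on accession could come from variants under probes designed on Col-0, from noisy arrays or from local genetic differences. Noisy arrays cannot be told apart from other causes. The share of these 2087 probe sets at which an accession lay farthest from the mean change had a Spearman rho of 0.10 (0.102) with its spread between replicates over 20 accessions, under the bound of 0.2 set beforehand, but 2 standard errors reach up to 0.53, and Cvi, with 1 array at EN, was farthest most often (13.1%). Probe variants cannot be told apart either, since Col-0 had the largest change at 8.62% of these probe sets against a median of 4.79% for the other accessions, but Cvi had 11.7%. Adjacent, here and below, means next to each other among 12354 named genes, so unnamed genes may lie between. Adjacent genes passed together more often than in random sets (19.9% against a median of 16.0%, with 95% of 10000 draws below 18.5%). The one-sided permutation p was 0.0066, and local sequence or copy differences might give such a result. The same held for the genes changed at least 2-fold over all accessions (14.3%, with 95% of draws below 13.5%), so shared local regulation may also contribute, and differences between the accessions in carbon use stay open and untested.

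The level differences at EN (8295 probe sets) were weighed against the same probe variants. The prediction for such variants, set beforehand, was that Col-0 would be the highest accession more often than any other. Col-0 was the highest at 3.57% of them, below the median of 4.3% of the other 19 accessions, so the prediction was not met. The test cannot decide, because a variant that lowers only a few accessions leaves the highest place open among all the others. Cvi and C24 were most often the highest (12.1% and 10.7%) and also most often the lowest (8.98% and 9.83%), and Col-0 was the lowest at 6.11%. Adjacent genes passed together more often than in random sets (63.2%, with 62.5% the highest of 10000 draws, one-sided permutation p = 1e-04), as local sequence or copy differences might give, so those stay open. For single genes, such as AT3G15310 and AT5G04380, a variant, an absent gene and a low level may each account for a low value, and no biological explanation was tested.

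Plastid-encoded transcripts were higher at EN than at ED with a median of 0.46 (59 of 65 passing upwards). If organelle RNA of every kind had entered the labelled material more at EN, mitochondrially encoded transcripts would have risen as much. Their median was 0.09 (0.0863 over 15 transcripts, with an upper bound of 0.21). That bound rests on the spread between transcripts, which are not independent replicates. After centring each array on its median the plastid median was still 0.45 (0.449). Centring could hardly have lowered it, as the median change of all probe sets only went from 0.006 to -0.0034. Whether plastid RNA alone entered the labelled material more at EN was not tested. A rise of plastid transcripts in the night itself is therefore only a hypothesis. The list calls behind it did not hold with an estimated correlation. For EN against ED 19 of 100 splits gave as many list calls as the real one. That count is over all lists, so it does not test the plastid lists by themselves.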

How the results depend on the processing

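The alternatives were planned except the sugar-repressed score, which stood in for the planned one, and the added gene lists. Each count of probe sets stayed within 1.5 times of the reported one under every alternative run. The larger direction was not stable. With array centring the share of higher calls went from 51% to 48.3% (EN against ED), from 47.5% to 54.1% (XN against EN) and from 47.6% to 51.1% (XN against ED), so the majority changed side in all 3, and without replicate 2 it was 49.9% for EN against ED. For EN against ED between 10484 and 12998 probe sets passed over array centring, renewed quantile normalization, the filter on dim probe sets, single arrays in 2 other models and moderated variances with trend. For XN against EN the range was 11358 to 14532, and for XN against ED 11900 to 15354, each lowest value coming from fewer probe sets tested. Without replicate 1 or without replicate 2 the ranges were 10728 to 10797, 12011 to 12500 and 13179 to 13553, and with each accession left out in turn 12080 to 12234, 13749 to 14063 and 14617 to 14878. With each array left out in turn, differences between accessions ranged from 9737 to 10910 at ED, 7845 to 8630 at EN and 9425 to 10225 at XN, interactions from 1960 to 2620 (ED to EN) and 1891 to 2344 (EN to XN), and the per-accession medians from 1111 to 1160 and 1594.5 to 1614.5.

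Gene lists depended on the test. Of 90 camera tests 26 passed, against 0 with an estimated correlation (lowest adjusted p = 0.0930, 15 at an unadjusted p under 0.05) and 75 with fry, which does not compare a list with other genes. Array centring gave 27, leaving out replicate 1 or 2 gave 25 to 27, and without the dimmest probe sets (the lowest 1 in 3 by mean) 21 of 84 passed, fewer genes being tested. There 20 of the 26 reported calls were kept: 4 missed the threshold (flavonoid and plastid NADH dehydrogenase-like at XN against EN, mitochondrial and plastid redox at XN against ED), and starch synthesis, at EN against ED and at XN against ED, was left with too few genes to test. Without replicate 2 the plastid NADH dehydrogenase-like call at XN against EN was lost. With array centring the flavonoid list passed at XN against ED too (adjusted p = 0.0491), as it did without replicate 1, and the vacuolar protease list passed there without the dimmest (adjusted p = 0.0449); the cause was not tested.

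Of 10184 alternative values of 352 named-gene changes 10035 kept direction and side of the threshold, 124 no longer passed, 19 passed where they had not, and 6 changed sign, in values that had not passed. Without replicate 1 or replicate 2, PYK10 ranged from -0.26 to 0.077 (XN against EN) and from -0.19 to 0.10 (XN against ED), EXPA7 from -0.027 to 0.17 (EN against ED) and from -0.078 to 0.014 (XN against ED), and PDF1.2 from -0.046 to 0.20 (XN against ED). PDF1.2 was -0.059 there without Mh1. Of the score relations, those that had not passed changed sign for ribosome assembly with the scores from different replicates (r = 0.25), and for nuclear photosynthesis transcripts with the scores from different replicates (r = 0.0013), array centring (0.032) and medians over members (0.097), and ranged from -0.20 to 0.14 with each accession left out; the causes were not tested.

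Replicate numbers did not pair the samples. The deviations of same-numbered arrays correlated with a median of -0.01 over 58 pairs of time points (from -0.42 to 0.26, 10 above 0.1). With the replicate number as a block, 12668, 14277 and 15168 probe sets passed in the 3 time comparisons (484 and 498, 714 and 710, 1169 and 1136 at least 2-fold higher and lower). As a random block it gave 10379, 8304 and 9859 differences between accessions at ED, EN and XN, interactions of 2008 and 1940, per-accession medians of 1125.5 and 1604.5, and a consensus correlation of -0.0222. The block gave 26 list calls, 25 of them among the reported 26, with the plastid NADH dehydrogenase-like list at an adjusted p of 0.0798 for XN against EN and the flavonoid list, not among the reported calls, at 0.0479 for XN against ED. Under the block AOP3 (EN against ED, adjusted p = 0.0331) and HYH (XN against ED, adjusted p = 0.0253) passed where they had not. Signal over background was not used here, so dim probe sets enter all counts.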

Other observations

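The test of the first against the second rise of the sugar-repressed score used a list added to the planned ones; the counts over splits of the samples were planned. Further groups were measured that the comparisons above have not described. At XN against EN, transcripts of protein quality control in the endoplasmic reticulum had 5 rises and 2 falls among 12, with DER2.1 and DER2.2, of a family of degradation factors there, at 1.17 and 0.61 and the folding factor ATERDJ3B at -0.42, and the camera adjusted p was 0.339. Stomatal lineage markers were 4, of which 3 fell and 1 rose (camera adjusted p = 0.414): the lineage transcription factors SPCH and FMA were at -0.41 and -0.36, and STOMAGEN, a signal peptide that promotes stomata, at 0.37. Among mitochondrially encoded transcripts 8 of 15 rose and 2 fell from EN to XN (median 0.13; camera adjusted p = 0.161), with cox1, a cytochrome oxidase subunit, at 1.5 and nad5 at 1.0, and at EN against ED 6 rose and 0 fell (camera adjusted p = 0.235). The vacuolar monosaccharide transporter TMT1 rose by 1.04 from EN to XN, in a family of 16 sugar transporters with 4 rises and 6 falls (camera adjusted p = 0.404). Of 18 auxin-related transcripts 7 rose and 5 fell (camera adjusted p = 0.349). Of 29 vacuolar proteases 2 rose and 10 fell (camera adjusted p = 0.263), with GAMMA-VPE at 0.47 and scpl46 at -1.59. Heat shock proteins and co-chaperones gave 3 rises and 3 falls of 10 (camera adjusted p = 0.957).

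At EN against ED, 3 of 13 transcripts of RNA polymerase subunits and rRNA processing rose and 10 fell (camera adjusted p = 0.236), with the rRNA methylase DIM1A at 1.26. Of 24 expansins and xyloglucan endotransglucosylases 9 rose and 6 fell (camera adjusted p = 0.727), and of the 5 fixed beforehand 3 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.957; 0.155 at XN against EN, with 1 rise and 3 falls). Of 4 cytosolic ribosomal proteins fixed beforehand 2 fell (2 when adjusted over the list alone; camera adjusted p = 0.395), and of 3 ribosome assembly factors 1 rose and 2 fell (also when adjusted over the list alone; camera adjusted p = 0.892). Of 13 autophagy transcripts 8 rose and 4 fell at EN against ED (also when adjusted over the list alone; median 0.32; camera adjusted p = 0.120), with ATG8E at 1.58, and of 8 for amino acid breakdown 5 rose and 1 fell (also when adjusted over the list alone; camera adjusted p = 0.395). Of 10 markers of pollen, egg cell, anther and inflorescence 1 rose and 2 fell (median 0.02; camera adjusted p = 0.993). Of 5 chlorophyll synthesis transcripts 3 rose and 1 fell (also when adjusted over the list alone), with a median of 0.09 and a mean of -0.29, because PORB fell by 2.3, and an upward but not passing test (camera adjusted p = 0.682). The wider tetrapyrrole list of 10 had 4 rises and 3 falls (camera adjusted p = 0.993).

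Among probe sets with no gene in the name table, 274 rose and 247 fell at least 2-fold at EN against ED. The 2 largest rises among them were 6.42 and 6.25, above the largest rise with a name (AT2G41250, 5.06), and the 2 largest falls were -5.69 and -4.59. At XN against EN 328 of them rose and 388 fell at least 2-fold, and at XN against ED 556 and 559.

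With time labels swapped within accessions at random, the count of passing probe sets was as large as the real one only in the real split, 1 of 100 in each comparison. This is the smallest share that 100 splits can give, so a random grouping seldom gives such a count. On fits to the 2 time points alone, the real and highest other counts were 12274 and 8871 for EN against ED, 14356 and 1 for XN against EN, and 14405 and 11933 for XN against ED, and the 2 high values came from splits that moved 3 of 20 accessions. For the number of gene lists passing at XN against ED, only the real split reached the real count (1 of 100 splits, 13 lists against 11). That is again the smallest share possible. This fit calls more lists than the 11 of the reported fit to 3 time points, so those 11 calls were not themselves tested. Chance was not excluded for EN against ED (19 of 100 splits, 7 lists against 10) or for XN against EN (12 of 100 splits, 8 lists against 11). The highest list counts there came from splits that moved 6 and 7 of 20 accessions. Such splits keep part of the real difference, so these counts cannot decide.

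A hypothesis was that accessions whose sugar-repressed transcripts are already high at EN rise less afterwards. The test set beforehand used the change from ED to EN in place of the level at EN. It therefore asks whether a larger first rise went with a smaller second one, and the level at EN was not itself tested. With replicate 1 at EN in the first change and replicate 2 in the second, the changes of the score from ED to EN and from EN to XN correlated at Pearson r = -0.60 (-0.603; permutation p = 0.00442) and Spearman rho = -0.45 (permutation p = 0.0548) over 19 accessions, the only relation of its family. With the replicates exchanged r was -0.55 (permutation p = 0.0109). Without the 2 accessions farthest from the median of the first change these r were -0.30 and -0.52, so how far the relation rests on those accessions depended on the split. A shared ceiling at XN is not shown: the score ranged over 0.58 there, 0.63 at ED and 0.96 at EN, where the top of the range, RRS7, rests on 1 of its 2 arrays. A negative r may also arise if differences at EN are simply not carried on to XN, since they enter both changes with opposite signs.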
